A study of Mus musculus with 3 samples.

How the data were processed

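RNA was sequenced from CD4+ T cells that bound 2W:I-A(b), sorted by flow cytometry from the inguinal and popliteal lymph nodes of C57BL/6 mice on day 7 after footpad immunization with 2W1S peptide, LPS and IFA. Per the labels' protocols, polyA-containing RNA went into the libraries. Cells were pooled from 4 experiments and from 15 to 30 mice per genotype. There were 3 libraries, 1 for each of the groups WT, MyD88 T-KO and IL6ra T-KO, grouped by their titles. Pooling averages over mice before sequencing, so the libraries hold no measure of the variation between mice.

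The authors deposited 2 tables, each comparing 1 knockout library with the WT library, each split over 4 sheets by the status of the gene. Expression is given in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers. TopHat and Cufflinks on genome build mm10 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The column names are those of a Cuffdiff gene table. The deposited log2 fold change is WT over knockout and was turned round here. The deposited test statistic, p-value and q-value of each gene are the authors' and compare 1 library with 1 library, not the genotypes. Each table covers 23283 genes or groups of genes, and 1 line without values in each table was left out. The authors tested 11164 of them in the MyD88 T-KO table and 11356 in the IL6ra T-KO table.

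The WT library stands in both tables with values that differ by a near-constant factor, with a median of 1.02 over 12993 genes. The tables were therefore scaled separately, and each knockout library was set against the WT values of its own table. Coordinates are those of the tables on mm10. For 10007 of the 20568 symbols on the same chromosome in the RefSeq gene table of the reference, the RefSeq start was 1 above the start in the tables, so starts were written with 1 added.

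The ratio reported for each gene is log2((knockout FPKM + 1)/(WT FPKM + 1)), which understates the difference of genes with low FPKM. A gene was counted as higher or lower at a log2 ratio of at least 1 in size, with FPKM of at least 5 in at least 1 of the 2 libraries. With 1 library per group there was no test and no p-value, and the counts describe these libraries. As an error for single genes, the standard error implied by the authors' deposited log2 fold change and test statistic is given as the implied SE. It belongs to the ratio without the pseudocount and comes from the authors' model, not from replicates.

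The 34 gene lists were T lineage, Th1, Th2, Th17, Tfh, Treg, proliferation G2M, DNA replication, IL-6 and STAT3 response, IL-1 and TLR pathway, NF-kB targets, T cell activation, inhibitory receptors, naive and central memory, cytotoxic and terminal effector, interferon response, apoptosis regulators, glycolysis, oxidative phosphorylation, sterol synthesis, unfolded protein response, homing and chemokine receptors, ribosomal proteins, dissociation and immediate early, markers of other cells (B cell, plasma cell, macrophage and dendritic, neutrophil, CD8 T cell, NK and innate lymphoid, gamma delta T cell, erythroid and platelet, stroma and endothelium) and sex-linked genes. Some genes stand on more than 1 list. For each list the median log2 ratio of members with FPKM of at least 1 in at least 1 library was set among the medians of 10000 random lists of the same size, drawn from 20 bins of mean log2(FPKM + 1). A list stood apart below percentile 2.5 or above percentile 97.5, and a list with fewer than 5 measured members was given by its median or its members, including members outside the naming rule below. Random lists hold genes that vary independently, while members of a list vary together, so a percentile describes these libraries and is no test of the genotype.

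The genes named are Myd88 and Il6ra. To these were added the 10 genes with the largest positive and the 10 with the largest negative ratio among tested genes with FPKM of at least 5, leaving out receptor segments, small RNA genes, predicted genes and entries with several symbols. Genes always included were, among others, Tbx21, Ifng, Gata3, Il4, Il17a, Bcl6, Cxcr5, Il21, Foxp3, Il2ra, Il2, Mki67, Gzmb, Socs3 and Nfkbia, and so were up to 2 members of each list in each direction. The lists, the size rule, this naming rule and all alternatives named in the closing section were fixed before the data were examined. Genes named outside the rule are marked as chosen after their values were seen.

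Depth was estimated from the FPKM of low genes with a single transcript, whose product with transcript length falls on steps of 1 fragment. It came to about 20.6 M fragments for MyD88 T-KO and 21.7 M for WT in the first table, and to 22.9 M for the library labelled IL6ra T-KO and 21.0 M for WT in the second. These totals include the authors' scaling, so the ratio to WT, 0.953 and 1.09, is firmer than the totals. Counting intervals are 95% intervals and cover counting error only.

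The computation was tested on simulated data drawn from the WT values and the authors' implied errors. In the MyD88 T-KO comparison, 7952 genes were simulated and genes changed by 2, 3 and 4 times passed the size rule in 38.8%, 100% and 100% of cases. In the IL6ra T-KO comparison, 8159 genes had simulated FPKM of at least 5 and the shares were 52.2%, 97.0% and 100%. Of the unchanged simulated genes, 59 and 202 passed the rule. Simulated lists of 20 members shifted by 0.4 stood apart in 100% of 100 draws in both comparisons, and unshifted ones in 8% (MyD88 T-KO) and 3% (IL6ra T-KO).

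The alternatives tried were pseudocounts of 0.1 and 5 FPKM, no FPKM minimum or one of 10, ratios shifted to a median of 0, upper-quartile scaling, only genes the authors tested, and counts without receptor segments, small RNA genes and markers of other cells. Further ones were counts limited to genes the authors marked significant, a stricter q-value of 0.01, list members of at least 5 FPKM, list means, 50 expression bins, and the 2 knockout libraries compared directly. Both comparisons share the WT library, so unchanged libraries sharing a WT library were simulated for the overlap. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.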

Results

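RNA levels were compared between wild-type mice and mice with MyD88 or the IL-6 receptor alpha chain deleted in T cells, in CD4+ T cells that recognize the immunizing peptide. MyD88 is the adaptor through which receptors of the IL-1 family and most Toll-like receptors signal. Il6ra encodes the chain of the IL-6 receptor that binds IL-6, a cytokine that signals through STAT3. The mice were immunized with 2W1S, a model peptide presented by the MHC class II molecule I-A(b), together with LPS, and cells binding 2W:I-A(b) were sorted on day 7. Each genotype was represented by 1 pooled library, so no difference reported here has a replicate check. Depth was estimated at 20.6 to 22.9 M fragments per library.

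The first comparison asked what T cells lacking MyD88 express differently after this immunization. Myd88 itself (chromosome 9, 119335988 to 119340040, mm10) stood at 19.5 FPKM in the MyD88 T-KO library and 49.8 FPKM in WT, a log2 ratio of -1.31 (implied SE 0.18), which is the direction its label names. In the authors' deposited table its q-value was 2.88e-11. Il6ra stood at 60.9 FPKM against 55.8 FPKM in WT, a ratio of 0.13.

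Cytokine genes of the Th17 program were lower in the MyD88 T-KO library than in WT. Il17f (chromosome 1, 20777146 to 20784270) was at 0.805 FPKM against 6.67 FPKM, a ratio of -2.09 (implied SE 0.48), and Il17a (chromosome 1, 20730905 to 20734496) at 1.73 against 7.60 FPKM, a ratio of -1.66 (0.40). Il22 (chromosome 10, 118204964 to 118210046), which encodes a cytokine acting on epithelia, was at 64.3 against 169 FPKM, a ratio of -1.38 (0.17). Its near-identical neighbour Iltifb had a ratio of -1.25, and reads of these copies may be divided between them. All 11 measured members of the Th17 list lay below 0, with a median of -0.40 at percentile 0 of the random lists. Of the 3 gamma delta T cell markers measured, Cd163l1 at -0.53 and 5830411N06Rik at -0.55 were lower too. The third, Blk, is also a B cell gene and was at 0.83. Gamma delta T cells can also make Il17a and Il22 transcripts, although the sort on CD4+ cells binding 2W:I-A(b) should remove them. Markers of B cells and CD8 T cells were measured despite that sort, so a gamma delta source stays open and was not tested.

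Th1 genes were lower as well. Ccl5, a chemokine gene, was at 19.1 against 47.8 FPKM, a ratio of -1.28 (implied SE 0.26), and Ifng at 6.07 against 12.2 FPKM, a ratio of -0.90 (0.29). Tbx21, the Th1 master regulator, had a ratio of -0.30 (0.28) at 2.95 against 3.87 FPKM. The Th1 list had a median of -0.36, with 11 of 13 measured members below 0, at percentile 0. The Th2 list had a median of -0.13 at percentile 1.12, with Il4 at -0.47 and Gata3 at -0.13. Its 7 measured members were divided, with 4 below 0 and 3 above. The Tfh list, of genes used by T cells that help B cells, had a median of 0.03 at percentile 48.0 and did not stand apart. Bcl6 had a ratio of 0.02, Il21 0.03 and Cxcr5 0.21. The Treg list had a median of -0.06 at percentile 0.75, with 11 of 19 members below 0 and 8 above, from Il10 at -0.68, Ctla4 at -0.66 and Foxp3 at -0.24 to Ebi3 at 0.27. It no longer stood apart when the mean of its members was used.

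Genes induced through NF-kB and by receptor stimulation were lower in part. Nfkbiz, an atypical inhibitor of NF-kB induced by IL-1 and Toll-like receptors, was at 38.1 against 89.8 FPKM, a ratio of -1.21 (implied SE 0.17). Tnfaip3, which encodes the feedback regulator A20, was at 156 against 279 FPKM, a ratio of -0.84 (0.20), and Nfkbia had a ratio of -0.43. The NF-kB list had a median of -0.10, with 15 of 20 members below 0, at percentile 0. The list of T cell activation genes also had a median of -0.10, at percentile 0.03, with Nr4a2 at -0.91 and Cd69 at -0.68, whereas Egr2 had a ratio of 0.08. The IL-6 and STAT3 list had a median of -0.29 at percentile 0, with Socs3 at -0.49 and Fos at -0.70. Of its 18 members, 7 stand on another list too, and Fos is counted again among the immediate early genes below. The list of IL-1 and TLR pathway components had a median of 0.01 at percentile 41.6, with Il18r1 at -0.58 and Tab1 at 0.10.

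Immediate early genes, which cells transcribe within minutes of stimulation or tissue handling, were lower with these groups. Their list had a median of -0.43, with 19 of 20 members below 0, at percentile 0. Fosb was at 59.7 against 127 FPKM, a ratio of -1.08 (implied SE 0.17), and Fosl2 at 9.33 against 19.9 FPKM, a ratio of -1.01 (0.17). Egr1 had a ratio of 0.01. The unfolded protein response list had a median of -0.08 at percentile 0.17, with Dnajb9 at -0.57, and the list of apoptosis regulators a median of -0.11 at percentile 0.02, with Pmaip1 at -0.68. Other genes far below WT were Camk2b at -2.11 (1.57 against 10.1 FPKM), Klf4 at -1.26 (18.1 against 44.8 FPKM) and Areg, which encodes the growth factor amphiregulin, at -1.14 (8.15 against 19.1 FPKM).

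Cell cycle genes were higher in the MyD88 T-KO library. All 26 members of the G2M list lay above 0, with a median of 0.39 at percentile 100. Ccnb1, which encodes cyclin B1, was at 10.5 against 5.84 FPKM, a ratio of 0.74 (implied SE 0.23), Ube2c had a ratio of 0.52, and the proliferation marker Mki67 0.44. The DNA replication list had a median of 0.17 at percentile 100, with Tk1 at 0.61. Smaller shifts upward were found for the lists of sterol synthesis (median 0.13, percentile 99.98), oxidative phosphorylation (0.08, percentile 99.46) and ribosomal proteins (0.08, percentile 99.47). The glycolysis list had a median of -0.08 at percentile 0.23. The sterol synthesis and glycolysis lists no longer stood apart when means were used.

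Markers of B cells were higher beside these groups. All 19 genes on the B cell list lay above 0, with a median of 0.83 at percentile 100. H2-Aa, an MHC class II gene, was at 156 against 78.1 FPKM, a ratio of 0.99 (implied SE 0.16), and Faim3 also had a ratio of 0.99 (0.20). H2-DMb2, a gene of class II peptide loading, had a ratio of 1.01. The CD8 T cell markers Cd8a and Cd8b1 had ratios of 0.88 and 0.82. The macrophage and dendritic cell list had a median of 0.25 at percentile 99.96, with Lyz2 at 0.96, and the plasma cell gene Igj had a ratio of 0.90, on a list of 4 measured members with a median of 0.22. The neutrophil list had a median of 0.01 at percentile 48.1. The 3 measured NK cell markers had a median of 0.20, and Pecam1, the 1 measured marker of stroma and endothelium, a ratio of -0.09. The hemoglobin genes Hba-a2 and Beta-s had ratios of 1.00 and 1.09. Hbb-b2 was at 5.51 FPKM and was listed at 0.00589 FPKM in WT, so no fold is given, and near-identical hemoglobin copies divide their reads.

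The remaining lists did not stand apart in the MyD88 T-KO library. Their medians were 0.02 for T lineage (percentile 28.8), 0.04 for inhibitory receptors (62.9), 0.04 for naive and central memory (76.4), 0.05 for cytotoxic and terminal effector (84.1), -0.03 for interferon response (6.45), -0.04 for homing and chemokine receptors (2.67) and -0.14 for sex-linked genes (6.04). The sex-linked list joins Xist with Y-linked genes, which a shift in sex balance would move in opposite directions, so its median could hide one. Xist was at 47.7 against 42.5 FPKM, while 3 of the 5 members lay below 0, down to -0.48. A difference in sex balance was not tested. Among 28 lists with at least 5 measured members, 18 stood apart, 7 higher and 11 lower, where random lists would give 5%.

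By the size rule, 15 genes were higher and 19 lower among 7933 genes with FPKM of at least 5. Of those higher, 7 were small RNA genes and 2 were markers of other cells, and of those lower, 4 were small RNA genes. Without receptor segments, small RNA genes and other-cell markers, 6 genes were higher and 15 lower. Outside the groups above, Gdpd3 was at 59.9 against 11.6 FPKM (2.27, implied SE 0.22), Erdr1 at 37.8 against 12.4 FPKM (1.53, 0.24) and Gstp2 at 22.8 against 8.38 FPKM (1.35, 0.30). Erdr1 and Gstp2 have near-identical copies, so their values are uncertain. The authors' deposited table marked 44 genes as significantly higher and 54 as lower between these libraries, and 14 of the higher ones were on the B cell list and 6 of the lower ones were immediate early genes. The authors' implied errors by themselves put 59 unchanged simulated genes past the size rule, more than the 15 and 19 observed together, so these errors are wider than the spread seen between the libraries for at least some genes, and the printed implied SEs share that limit. The balance turned with a pseudocount of 0.1 FPKM, to 27 higher and 22 lower, and was even with one of 5 FPKM, at 10 each.

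The second comparison asked what T cells lacking the IL-6 receptor alpha chain express differently. Il6ra (chromosome 3, 89869324 to 89913162, mm10) stood at 65.1 FPKM in the library labelled IL6ra T-KO and 57.1 FPKM in WT, a log2 ratio of 0.18 (implied SE 0.27), so the transcript was not reduced as the label would have it. The values cover the whole gene, and a deletion that removes some exons could leave them. All directions below are those of the library labelled IL6ra T-KO against WT. Myd88 stood there at 34.2 against 51.0 FPKM, a ratio of -0.56 (0.28).

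Genes induced by IL-6 through STAT3 were lower in the library labelled IL6ra T-KO. Socs3 (chromosome 11, 117966087 to 117969366), a feedback inhibitor of IL-6 signalling, was at 37.9 against 169 FPKM, a ratio of -2.13 (implied SE 0.28). Socs1 had a ratio of -1.58 (0.29) and Bcl3 -1.16 (0.28). The IL-6 and STAT3 list had a median of -0.37, with 13 of 18 members below 0, at percentile 0. The 5 members above 0 included Ifitm3 at 1.40 and Tnfrsf1b at 0.61, and Ifitm3 is also induced by interferon.

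Th17 genes were lower by larger amounts. Il22 was at 3.10 against 173 FPKM, a ratio of -5.41 (implied SE 0.48), and Iltifb had a ratio of -3.20 (0.64), with the same doubt about divided reads. Il17a was at 1.23 against 7.79 FPKM, a ratio of -1.98 (0.63). Il17f was at 0.107 FPKM, an estimated 2.46 fragments, against 6.83 FPKM, so WT was 63.9 times higher with a counting interval of 21.4 to 655. Il1r1 (chromosome 1, 40225080 to 40316177), which encodes the IL-1 receptor on Th17 cells, was at 13.0 against 70.8 FPKM, a ratio of -2.36 (0.29). Ahr had a ratio of 0.61. The Th17 list had a median of -1.03, with 10 of 11 measured members below 0, at percentile 0. The gamma delta T cell marker Cd163l1 moved the same way, with a ratio of -2.15 (0.62), and 5830411N06Rik was at -0.99, while Blk was at 0.52.

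Th1, cytotoxic and interferon genes were higher in the library labelled IL6ra T-KO. Tbx21 was at 10.3 against 3.96 FPKM, a ratio of 1.18 (implied SE 0.39), and Ifng at 27.7 against 12.5 FPKM, a ratio of 1.09 (0.39). The Th1 list had a median of 0.44, with 12 of 13 measured members above 0, at percentile 100. The authors' deposited table marked no measured member of it as significant, Tbx21 and Ifng included. The cytotoxic and terminal effector list had a median of 0.67, with 20 of 23 members above 0, at percentile 100. It included Klrd1, an NK cell receptor gene, at 1.80 (0.70), Ctsw at 1.55 (0.48) and Gzmb at 0.41 (0.28). All 32 interferon response genes lay above 0, with a median of 0.43 at percentile 100, and among them Gbp3 had a ratio of 1.13 and Oasl2 0.95. Ifitm1 and Ifitm2, membrane proteins that restrict viral entry, had ratios of 2.38 (25.6 against 4.09 FPKM) and 1.94 (28.5 against 6.68 FPKM). The Th2 list had a median of 0.30 at percentile 99.7, with Il1rl1 at 1.09, Gata3 at 0.46 and Il4 at -0.04. Its 7 measured members were divided, with 4 above 0 and 3 below.

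Regulatory T cell genes were higher on balance. Foxp3, the Treg lineage factor, was at 36.8 against 26.1 FPKM, a ratio of 0.48 (implied SE 0.29), Il2ra at 35.1 against 19.5 FPKM, a ratio of 0.81 (0.28), and Ebi3, which encodes a subunit of IL-35, was at 15.9 against 4.97 FPKM. Of these genes the authors' deposited table marked only Ebi3 as significant. The Treg list had a median of 0.37, with 15 of 19 members above 0, at percentile 100. Folr4 at -1.15 and Tigit at -0.92 went the other way, and both are also high in follicular helper cells. The Tfh list had a median of -0.20 at percentile 10.9 and did not stand apart, although its mean, -0.28, did. Within it Il21 was at 43.1 against 91.5 FPKM, a ratio of -1.07 (0.27), Cxcr5 at 122 against 213 FPKM, a ratio of -0.80 (0.29), and Bcl6 at 67.0 against 63.9 FPKM, a ratio of 0.07 (0.27).

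Proliferation genes were higher here too. All 26 G2M genes lay above 0, with a median of 0.62 at percentile 100, and Mki67 was at 34.1 against 20.8 FPKM, a ratio of 0.69 (implied SE 0.28). No G2M gene was marked significant in the authors' deposited table. The DNA replication list had a median of 0.35 at percentile 100, with Tk1 at 0.74. Homing and chemokine receptors had a median of 0.17 at percentile 100, with Gpr15 at 1.51, Cxcr6 at 0.69 and Ccr6 at -0.84. Lower lists were ribosomal proteins (median -0.25, percentile 0.15), unfolded protein response (-0.24, percentile 0.22) and glycolysis (-0.23, percentile 0.865), the last of which did not stand apart by its mean. Immediate early genes had a median of -0.43 at percentile 0, with Fosl2 at -1.25 (0.29) and Junb at -0.98 (0.37).

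Markers of other cells differed in both directions in the library labelled IL6ra T-KO. All 19 B cell genes lay above 0, with a median of 0.51 at percentile 100. Igj was at 42.2 against 8.16 FPKM, a ratio of 2.24 (implied SE 0.35), on a plasma cell list with a median of 0.63 at percentile 99.9. The macrophage and dendritic list had a median of 0.58 at percentile 100, with Lyz2 at 0.72. All 5 measured neutrophil genes lay below 0, with a median of -0.85 at percentile 0.01, and S100a8 was at 11.1 against 19.4 FPKM. Mpo, left out of that list by the FPKM minimum of 1, was at 0.798 against 0.0329 FPKM. The authors marked it as higher, and it was chosen after its values were seen. The CD8 T cell markers had a median of 0.24, the 3 NK cell markers 0.26, and Pecam1 a ratio of -0.05. Sex-linked genes had a median of 0.82 at percentile 100, and the X-linked Xist had a ratio of 0.19. The Y-linked genes Eif2s3y and Ddx3y were at 15.7 against 3.96 FPKM and at 10.5 against 4.56 FPKM. WT held Xist too, at 42.5 FPKM in the first comparison, so its pool may hold mice of both sexes. The sex of the mice is not among the sample information used here. In either comparison, a sex balance that differs between the pools could not be told apart from the genotype and was not tested. Hba-a2 was listed at 0.000477 FPKM against 6.15 FPKM in WT. At the same coordinates the entry naming both Hba-a1 and Hba-a2 was at 5.84 FPKM and listed at 0.000214 FPKM in WT, and the sum of these entries had a ratio of -0.06.

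The lists that did not stand apart had medians of -0.16 for T lineage (percentile 49.0), -0.03 for IL-1 and TLR pathway (47.2), -0.13 for NF-kB targets (14.5), -0.08 for T cell activation (40.3), 0.02 for inhibitory receptors (95.9), -0.11 for naive and central memory (28.8), -0.04 for apoptosis regulators (59.0), -0.10 for oxidative phosphorylation (59.9) and -0.09 for sterol synthesis (8.50). Members that differed within them included Satb1 at -1.40 (implied SE 0.29), Il7r at 0.93, Nfkbia at -0.76, Fas at -1.08, Entpd1 at 1.11 and Ccl3 at 1.47. Among 29 lists, 19 stood apart, 12 higher and 7 lower.

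By the size rule, 77 genes were higher and 60 lower among 8100 genes, whose median ratio was -0.06. Under upper-quartile scaling the split was 100 higher and 45 lower. Small RNA genes made up 6 of those higher and 5 of those lower, and the alpha globin entries put 1 gene on each side. Genes outside the groups above included Stom (6.58 against 38.9 FPKM, -2.39), Vwde (-2.19) and Gdpd3, at 0.440 against 11.9 FPKM (-3.16), on the lower side. On the higher side were the histamine receptor gene Hrh4 (2.32), Fam71b (1.77), the neighbours Chdh (2.09) and Il17rb (1.90) on chromosome 14, and Nrn1 (53.7 against 15.3 FPKM). The authors' deposited table marked 57 genes as significantly higher and 53 as lower. The authors' implied errors put 202 unchanged simulated genes past the rule, more than the 77 and 60 together, with the same bearing on the implied SEs. The balance turned with a pseudocount of 5 FPKM, to 32 higher and 35 lower, and among genes the authors marked significant, to 35 higher and 45 lower. It was 116 higher and 79 lower with no FPKM minimum, and 49 higher and 47 lower with a minimum of 10.

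**Figure D1:**
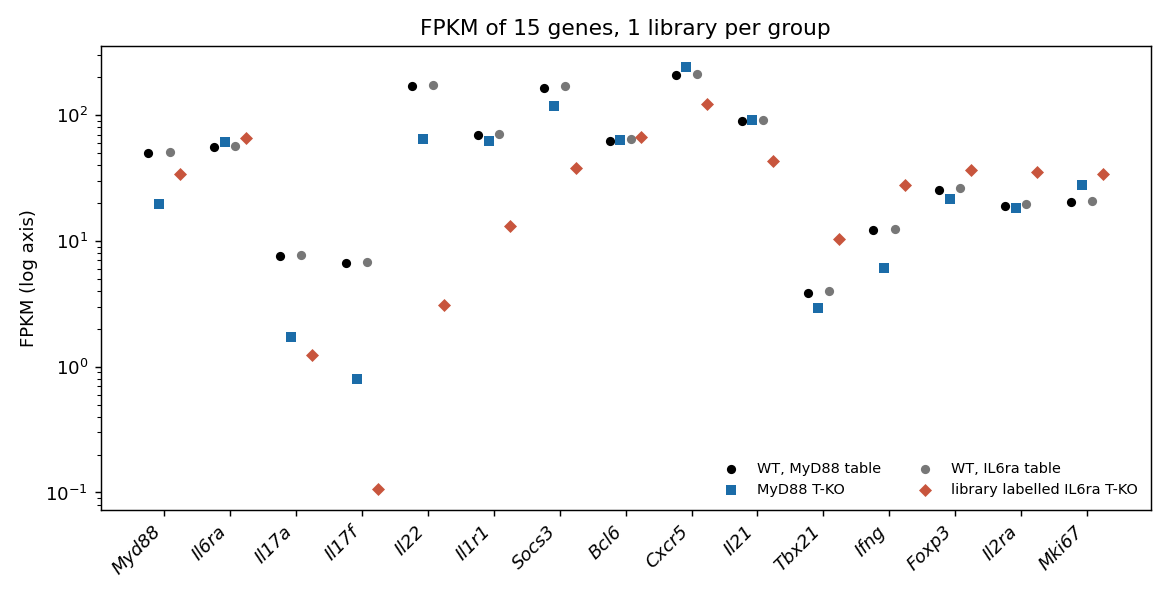
FPKM (log axis) of 15 genes, 1 point per library, with WT shown once as it stands in each table. Il22 lies at 169 and 173 FPKM in WT, 64.3 in MyD88 T-KO and 3.10 in the library labelled IL6ra T-KO, while Il6ra lies between 55.8 and 65.1 FPKM in all of them.

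**Figure D2:**
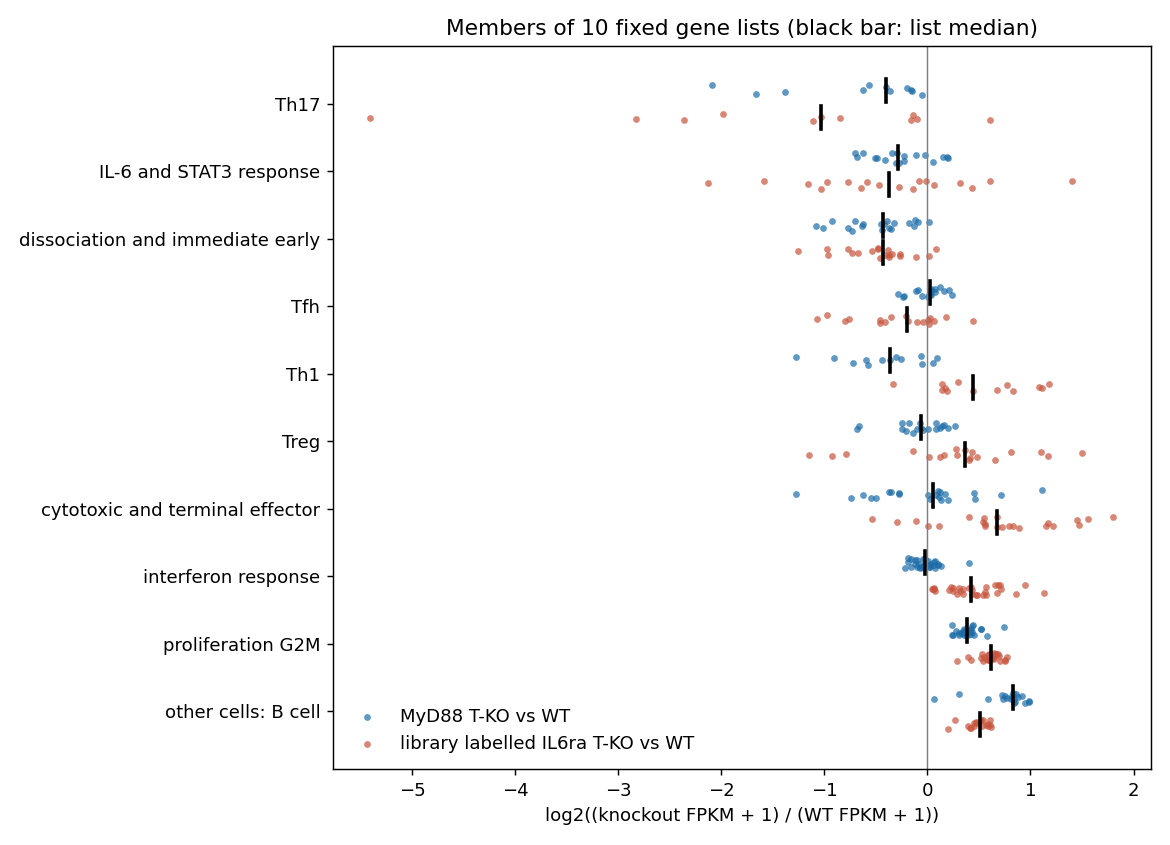
Log2((knockout FPKM + 1)/(WT FPKM + 1)) of the measured members of 10 gene lists, 1 point per gene, for MyD88 T-KO and for the library labelled IL6ra T-KO, with black bars for list medians. The Th1 median lies at -0.36 in MyD88 T-KO and 0.44 in the library labelled IL6ra T-KO, and the Th17 median below 0 in both.

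The third comparison set both knockout libraries side by side. Genes lower by the size rule in both numbered 10, namely Il17a, Il17f, Il22, Iltifb, Areg, Fosl2, Lif and the small RNA genes Mir669i, Snora28 and Snora70. Genes higher in both numbered 2, Gstp2 and Oaz1-ps. Higher in MyD88 T-KO and lower in the library labelled IL6ra T-KO were 3 genes, Erdr1, Gdpd3 and Hba-a2, the last only through the divided entries above. The authors' deposited tables marked as lower in both a total of 9 genes, with Cpe and Maff added and the small RNA genes absent, and 1 higher in both, Igj. Lif, Oaz1-ps, Cpe, Maff and the small RNA genes fall outside the naming rule and were named after their values were seen.

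The Th17 list was lower still in the library labelled IL6ra T-KO than in MyD88 T-KO, with a median difference of -0.40 at percentile 0. Its lowest member was Il22, with a difference of -4.03. Higher in the library labelled IL6ra T-KO than in MyD88 T-KO were the lists of Th1 (median difference 0.71), Th2 (0.59), Treg (0.44), cytotoxic genes (0.76), interferon response (0.47, 32 of 32 members), T cell activation (0.22), homing and chemokine receptors (0.23), G2M (0.21), DNA replication (0.14), sex-linked genes (1.30), plasma cell (0.41) and macrophage and dendritic (0.25). NF-kB targets (0.00) and apoptosis regulators (0.06) stood above most random lists, whose medians lay mainly below 0. Lower there were ribosomal proteins (-0.34), B cell (-0.34), neutrophil (-0.72), sterol synthesis (-0.22), glycolysis (-0.22) and naive and central memory genes (-0.21). Plasma cell, glycolysis and naive and central memory no longer stood apart under 1 alternative each. The IL-6 and STAT3 list had a median difference of -0.19 at percentile 8.92 and the immediate early list one of -0.06 at percentile 96.5, so neither stood apart between the knockout libraries.

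Both comparisons use the same WT library, so chance values of that library enter both. Across 8157 genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.279, a Spearman rho of 0.322 and a covariance of 0.0256. Unchanged libraries simulated with the authors' implied errors gave a mean r of 0.155, a covariance of 0.0580, and 10.1 genes higher and 15.7 lower in both. Simulated with counting error only they gave a mean r of 0.502, a covariance of 0.00351, and 0.02 genes in each direction. The observed covariance differed from these by -0.0323 and 0.0221. Independent lists of the observed sizes would share 0.142 genes higher and 0.140 lower. The implied errors gave a covariance above the whole observed variance of the MyD88 T-KO ratios, 0.0554, so they were too wide for these libraries. Counting error leaves out all other variation between libraries. That the observed overlap lay below one simulated value and above the other therefore decides nothing about a shared effect. The WT library cannot be split, and part of any excess may come from it.

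**Figure D3:**
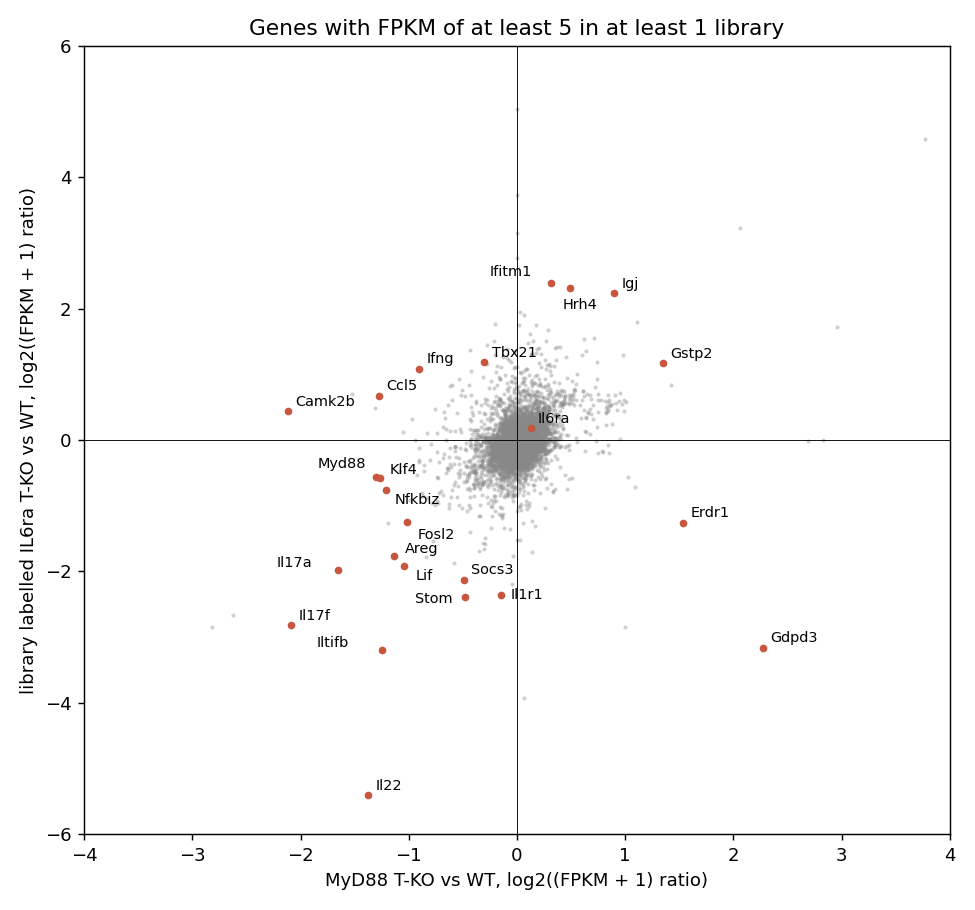
Log2 ratio against WT in MyD88 T-KO (horizontal axis) and in the library labelled IL6ra T-KO (vertical axis) for 8157 genes with FPKM of at least 5 in at least 1 library, 1 point per gene, with named genes in red and 6 genes outside the axes. Il22 lies at -1.38 and -5.41, Gdpd3 at 2.27 and -3.16.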

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

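All tests of explanations in this part were chosen after the results were seen, and the way the heat shock, knockout-exchange and deletion tests are read was revised after their values were seen. The following groups and genes drew attention because the knockout libraries lay on opposite sides of WT, and none of these differences was tested, since each rests on 1 library per group. The Th1 list had medians of -0.36 in MyD88 T-KO and 0.44 in the library labelled IL6ra T-KO, the Th2 list -0.13 and 0.30, the Treg list -0.063 and 0.37, and the ribosomal protein list 0.081 and -0.25. Of the 7 measured Th2 members, 3 lay above 0 in MyD88 T-KO and 4 in the library labelled IL6ra T-KO, so that list did not reverse as a whole. Gdpd3 had ratios of 2.27 and -3.16 and Erdr1, a gene with several copies, 1.53 and -1.26. Hba-a2 had ratios of 1.00 and -2.84, but the second came from the division of reads between overlapping entries, whose sum had ratios of 1.00 and -0.06.

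The first pattern weighed was the height of B cell genes in both knockout libraries, with list medians of 0.83 and 0.51. A lower share of T cells would raise the markers of all other cells alike. Among neutrophil markers with FPKM of at least 1, however, the highest lay below the lower quartile of the B cell list. The gap was 0.52 in MyD88 T-KO and 0.94 in the library labelled IL6ra T-KO. Mpo, a neutrophil gene below that minimum, went the other way in the latter, at 0.798 against 0.0329 FPKM. The neutrophil genes were thus not uniform there. More B cells, or their RNA, in the sorted pools are a candidate explanation, and more of some other cells stays open too, since in MyD88 T-KO Cd8a (0.88), Cd8b1 (0.82), Lyz2 (0.96, on a macrophage and dendritic list with a median of 0.25) and the sums of the alpha and beta globin entries (1.00 and 1.15) were also higher. A second list of 26 B cell genes, written after several of its members had been seen among the authors' calls and so not independent, had medians of 0.63 (26 of 26 above 0) and 0.40 (24 of 26), and Cd74 stood at 382 against 201 FPKM in MyD88 T-KO (Cd74, Cd22 and Pax5 were chosen after their values were seen). The gate on CD4+ cells binding 2W:I-A(b) should remove B cells and the other cells named above alike. Cd22 (0.07) and Pax5 (0.31) were among the weakest members in MyD88 T-KO. Blk is also a gamma delta T cell gene, and T cells also express Faim3. A difference linked to the genotype stays open, untested.

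The second pattern was the lower level of immediate early genes in both knockout libraries, with a median of -0.43 in each. A high value in the shared WT library predicts little difference between the knockouts for each member. The median difference was -0.059, inside the random range at percentile 96.5, though outside it with an FPKM minimum of 10. Single members differed by -0.50 to 0.61, with quartiles of -0.26 and 0.37. The median alone therefore does not show like amounts gene by gene, and this explanation stays undecided. An effect common to both deletions predicts a like median and stays open too, because WT is 1 library. Handling stress as a whole should lower the heat shock members too, whose median was -0.35 at percentile 0.05 in MyD88 T-KO against -0.63 for the other members, and -0.26 at percentile 11.2 in the library labelled IL6ra T-KO against -0.48. The first goes with this explanation, the second is inside the random range, and with 5 heat shock genes it stays undecided.

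The third pattern was the Il6ra transcript, which was not reduced in the library whose label names its deletion. An exchange of the knockout libraries would put the lower Myd88 value there, but the Myd88 ratio was higher by 0.74 (implied SE 0.33) than in MyD88 T-KO. An exchange with WT would put IL-6 and STAT3 genes above WT, but their median was -0.37, though that list was also at -0.29 in MyD88 T-KO. A deletion that leaves most of the transcript could give the ratio of 0.18 (implied SE 0.27), and so could cells that kept the gene or a wrong label of another kind. Values over the whole gene do not separate these, and single exons were not analysed here.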

How the results depend on the processing

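The alternatives were chosen before the data were examined, and no list that stood apart and no named gene past the size rule changed direction under those run. The balance of genes higher and lower did turn under some. Some values near 0 changed sign, among them Il4 and Pecam1 in the library labelled IL6ra T-KO under upper-quartile scaling and a median of 0, and medians of lists that did not stand apart. Where a cause is not named below, the cause was not tested. With a pseudocount of 0.1 FPKM the 15 genes higher and 19 lower in MyD88 T-KO became 27 and 22. With a pseudocount of 5 FPKM they became 10 and 10, the 77 higher in the library labelled IL6ra T-KO became 32, its 60 lower became 35, and the overlap of 12 became 5, since a larger pseudocount shrinks the ratios of low genes. With no FPKM minimum 116 genes were higher in the library labelled IL6ra T-KO and with a minimum of 10 there were 49, as more or fewer genes enter. Without receptor segments, small RNA genes and other-cell markers 6 genes were higher in MyD88 T-KO. Counting only genes the authors marked significant, 5 were higher and 13 lower in MyD88 T-KO, and 35 higher and 45 lower in the library labelled IL6ra T-KO. The authors' calls went from 98 to 61 (MyD88 T-KO) and from 110 to 55 (IL6ra T-KO) at a q-value of 0.01, and to 21 for MyD88 T-KO with a log2 ratio of at least 1. Upper-quartile scaling moved the median of genes with FPKM of at least 5 by 0.01 and 0.09. The direct comparison of the knockout libraries gives no value for the overlap.

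List medians kept their side of the limit in 159 of 165 settings for MyD88 T-KO, 165 of 170 for the library labelled IL6ra T-KO and 108 of 112 for their difference. Using means ended the calls of Treg, glycolysis and sterol synthesis in MyD88 T-KO and of glycolysis in the library labelled IL6ra T-KO. It also made homing and chemokine receptors stand apart in the former, as did a pseudocount of 5 FPKM, and Tfh, NF-kB targets and sterol synthesis in the latter. With members of at least 5 FPKM, IL-1 and TLR pathway genes stood apart in MyD88 T-KO and sterol synthesis in the library labelled IL6ra T-KO. Between the knockout libraries, a pseudocount of 5 FPKM ended the plasma cell call, and a minimum of 10 FPKM ended those of naive and central memory and glycolysis and made immediate early genes stand apart. Of the values of named genes, 16 of 508 and 28 of 504 moved by more than 1 implied SE, all with another pseudocount. The median shift and upper-quartile scaling moved the median ratio by at most 0.01 in MyD88 T-KO and 0.09 in the library labelled IL6ra T-KO. The median implied SEs were 0.18 and 0.32, so these 2 settings could hardly move a value that far. No paired analysis was possible because each group has 1 library. Depth limits genes of few fragments, such as Il17f at 2.46 in the library labelled IL6ra T-KO.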

Other observations

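The tests of flanking DNA in this part were chosen after the results were seen, and their reading was revised once their values were known. Embryonic stem cell DNA of another strain around a targeted gene could alter the levels of its neighbours. Within 20 Mb of Myd88 lay 0% of the 33 other genes past the size rule in MyD88 T-KO (95% interval 0 to 10.6), where 1.64% of genes lie. Within 20 Mb of Il6ra lay 0.73% of the 137 in the library labelled IL6ra T-KO (0.0185 to 4.00), where 2.46% lie. Flanking DNA thus does not account for most of these genes, and a small contribution stays open.

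Some genes outside the naming rule, chosen after their values were seen, differed in the library labelled IL6ra T-KO. Among those below, Nkg7 is on the cytotoxic list and Batf on the IL-6 and STAT3 list, so both already entered those medians. Iigp1, which encodes an interferon-inducible GTPase, was at 12.8 against 4.27 FPKM (1.39), Gbp6 at a ratio of 1.26, Gbp7 at 1.19 and Gbp10 at 1.22. These 4 genes are no fixed list and say nothing of their family, and their ratios in MyD88 T-KO were 0.18, -0.12, -0.06 and -0.07. Nkg7, a cytotoxic granule gene, was at 71.0 against 25.3 FPKM (1.45), and in MyD88 T-KO at -0.27. Il10ra (1.27), Il9r (1.42), Zbtb32 (1.41) and Fgl2 (1.38) were also higher. Batf, a transcription factor gene of Th17 cells, was at 83.0 against 171 FPKM (-1.03), and App at -1.87. Gstp1, the near-identical neighbour of Gstp2, had a ratio of 0.48 in MyD88 T-KO and -0.08 in the library labelled IL6ra T-KO.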
